A study of Homo sapiens with 8 samples.

How the data were processed

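Total RNA from HCT116-/- cells, which the labels describe as colon cancer, and from MIAPaCa2 cells was measured on 8 Agilent 1-colour expression arrays, after transfection with the microRNA miR-766-5p or with a negative control (miR-NC), with 2 arrays in each of 4 groups. Per the labels' protocols, RNA was treated with DNase, labelled with Cy3 after linear amplification and hybridised. What the suffix of HCT116-/- stands for, the dose and the time after transfection are not given in the sources used here. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

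The deposited scanner files give an intensity for each spot. Per the file headers they were written by Agilent Feature Extraction 12.0.1.1, and per the submitters' processing notes by version 9.1. The column used was the processed signal, which per the file headers is the background-corrected spot intensity on a linear scale. The authors also deposited a table of log2 values. In that deposited table each column equalled the log2 processed signal minus a constant of its array for at least 99.27% of the probes, within a tolerance of 0.01. Genes were not centred there, and its direction is that of the signal. How the constant was chosen stays unknown. The column medians of that table lay between -0.45 and -0.42.

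For each array, log2 of the processed signal minus the array's 75th percentile over noncontrol spots was computed. Control spots and spots marked as outliers were left out, and spots of the same probe were averaged. A probe was tested where it was well above background on both arrays of at least 1 group, which left 23374 of 50599 probes. The files hold no gene symbols, so probes were named through their accessions and a RefSeq table of the GRCh38.p14 assembly. It matched 30275 probes to 1 gene, 21743 genes in all, and 20324 probes kept the accession of the file. No coordinates of that assembly are printed, because the array was designed on another one. A gene with several probes was represented by the one with the highest mean over the 8 arrays. This gave 18549 features, of which 14037 carried a gene symbol, and all of them are called genes below.

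Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05). The fit had 1 mean for each of the 4 groups, 4 residual degrees of freedom and no covariate. Contrasts compared miR-766-5p with miR-NC within each line, the response of MIAPaCa2 with that of HCT116-/-, and the miR-NC arrays of the lines. An additive fit of cell line and transfection tested the change over both lines. Errors are the standard errors of the fit (SE), and n is 2 arrays per group unless stated. Where a probe was well above background on both arrays of 1 group and on no array of the other, the change has only a bound. It sets the mean of the brighter group against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. It is written as at least that many fold.

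The design, the 30 gene lists and the rule for named genes were fixed before the data were examined. Within a line, the rule takes the 10 largest rises and the 10 largest falls among genes with a symbol that pass the threshold, are well above background on all 4 arrays of the line, are not saturated, and have both miR-766-5p arrays on the same side of both miR-NC arrays. It also takes the 3 largest bounds each way, the 10 largest mean changes each way shared by the lines, the 5 largest differences each way between responses and between lines, up to 4 members of a list by smallest adjusted p, and genes named in advance, CREBBP and MYC among them. A gene that the rule names and a list are not reported here. Lists with at least 5 tested members were tested with limma's camera with a preset correlation of 0.01, and 25 of the 30 reached that size. An estimated correlation and fry stood beside it. The lists reported were super-enhancer coactivators, MYC targets, histone and HEXIM1 genes, mitosis, DNA replication, p53 targets, CDK inhibitors, BCL2 and IAP families, interferon response, unfolded protein and amino acid stress, heat shock, cholesterol synthesis, NF-kB response, epithelial and mesenchymal markers, Wnt targets, immediate early and MAPK feedback genes, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, lysosome and autophagy, NRF2 targets, miRNA machinery, housekeeping genes, and markers of colon epithelium, pancreas and duct, fibroblasts, leukocytes and endothelium. A planned test of 3' UTR seed sites was not run, because no UTR sequences were used here.

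The number of arrays limits the precision. Between 39.9% and 49.0% of the 58717 noncontrol spots of an array were well above background, and none were saturated. All 8 arrays lay on 1 slide with 1 scan day, so neither can act as a batch. Array columns 1 and 2 held the miR-NC samples and columns 3 and 4 the miR-766-5p samples of both lines, so position on the slide and transfection cannot be told apart by design. Array row 1 held HCT116-/- and row 2 MIAPaCa2, so slide row and cell line cannot be told apart either. The procedure was tested on simulated data with 18541 genes and the spread of the real arrays. In the HCT116-/- comparison it recovered 20.9% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 80.3% of those changed 4-fold, with 6 false calls. For the difference between responses it recovered 5.97%, 28.4% and 71.2% at the same folds, with 4 false calls. Over both lines it recovered 62.7%, 68.7% and 90.9%, with 9 false calls. Only 67, 67 and 66 simulated genes were changed at these folds, whereas 10456 of 18549 passed in the real HCT116-/- comparison. With so few changed genes the adjusted threshold falls at a smaller p, so these recoveries do not describe the real data. Camera recovered 5 of 5 shifted lists and called 0 of the others, at a simulated shift of 0.5 (log2). The simulated noise was independent between genes, so this could not test correlation within lists, on which the list results below depend.

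Alternatives were quantile normalization, normexp background correction with an offset of 50 (on the median spot signal, since the mean signal is not a column of these files), the authors' table, other filters on dim probes, the mean of a gene's probes, fits on the arrays of 1 line, an intensity trend in eBayes, the replicate number as a block, tests against a fold change, spots marked as outliers kept, and leaving out each array. Scaling to the spike-in controls was chosen after seeing the data.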

Results

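Gene expression was measured on 8 arrays from 2 cancer cell lines, HCT116-/- and the pancreatic cancer line MIAPaCa2, transfected with miR-766-5p or with a negative control. Each of the 4 groups had 2 arrays. The question, per the series' title, was which genes miR-766-5p alters in these lines. The 75th percentile of the signal was 318 and 332 on the HCT116-/- miR-NC arrays and 212 and 216 on the miR-766-5p arrays. In MIAPaCa2 it was 264 and 234 on the miR-NC arrays and 186 and 177 on the miR-766-5p arrays. The 2 arrays of a group correlated at r = 0.992 (HCT116-/- miR-NC), 0.990 (HCT116-/- miR-766-5p), 0.990 (MIAPaCa2 miR-NC) and 0.990 (MIAPaCa2 miR-766-5p) across genes, which are not independent replicates. Over the 518 probes compared for this, the spread of the difference between the 2 arrays of a group was 1.17 to 1.64 times that which the spots within an array give.

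CREBBP, a histone acetyltransferase, was lower after miR-766-5p in both lines. In HCT116-/- CREBBP fell by 1.78 (log2; SE 0.08, n = 2 per group; limma adjusted p = 6.8e-05). It was not well above background on the MIAPaCa2 miR-766-5p arrays and was at least 1.77-fold lower there. MYC, a transcription factor of growth genes, fell by 1.15 in HCT116-/- and by 0.91 in MIAPaCa2 (SE 0.07 in each). CREBBP was named in advance from general knowledge of this microRNA and not from the labels or files. That knowledge may include work of the group that deposited these arrays, so its fall is not independent evidence.

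**Figure D1:**
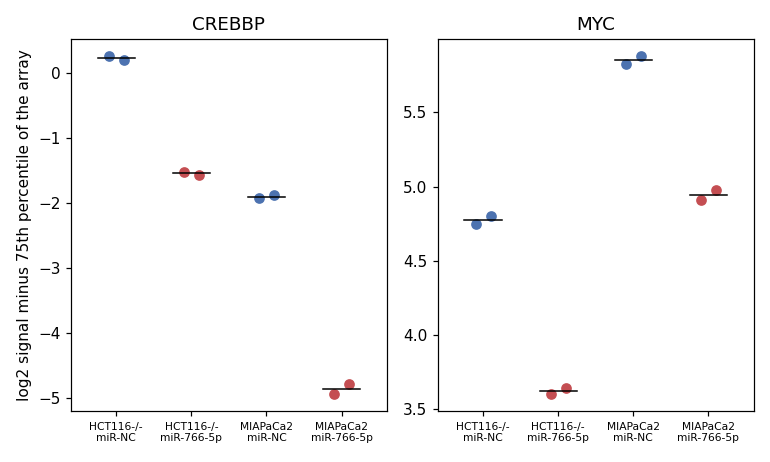
Log2 signal minus the array's 75th percentile (y axis) of CREBBP and MYC on each of the 8 arrays, by group (x axis), with points for arrays and lines for group means. MYC lay at 5.82 and 5.88 on the MIAPaCa2 miR-NC arrays and at 4.91 and 4.98 on the miR-766-5p arrays.

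Among genes with a symbol that were well above background on all 4 arrays of HCT116-/-, 7 of the 10 largest rises were of small nucleolar RNAs of the H/ACA class, which guide pseudouridylation. SNORA30 rose 16.95-fold (log2 4.08, SE 0.08, n = 2 per group), SNORA2B 12.9-fold, SNORA48 12.1-fold, SNORA67 11.9-fold, SNORA6 10.6-fold, SNORA13 10.3-fold and SNORA51 9.94-fold. MGAT4A, a glycosyltransferase, rose 13.8-fold, FRZB, a secreted Wnt antagonist, 10.1-fold, and CA8 9.89-fold. Among the same genes the largest fall was that of NUPR1, a stress-induced nuclear protein, by 3.54 (log2; SE 0.07). SLC25A10, a mitochondrial dicarboxylate carrier, fell by 3.45, PLP2 by 3.25, TPGS2 by 3.22, R3HDM2 by 3.11, RECQL5, a DNA helicase, by 2.97, LYPLAL1 by 2.93, BCAT2, a branched-chain aminotransferase, by 2.92, ABCC3, an efflux transporter, by 2.92 and IDNK by 2.91. The limma adjusted p of these genes lay between 4.8e-05 and 6.9e-04. Of genes measured in only 1 group, ANKRD26P1 was at least 17.3-fold higher, LINC01191 at least 17.0-fold and LINC01140 at least 6.76-fold, while KRCC1 was at least 8.02-fold, STRA6 at least 7.71-fold and PIGZ at least 7.33-fold lower. The other probe gave 0.04 for STRA6 (limma adjusted p = 0.92), -0.51 for RECQL5 (limma adjusted p = 0.056) and -2.86 for ABCC3, and that of LINC01191 was also higher (limma adjusted p = 0.011).

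Of 18549 genes, 10456 passed in HCT116-/-, 5883 of them higher and 4573 lower with miR-766-5p. At least 2-fold changes made up 1926 and 2019 of these. The split depends on the scaling and on the filter. With arrays scaled to the spike-in controls, chosen after seeing the data, 2557 were higher and 7682 lower. After quantile normalization 4909 were higher and 5186 lower, and after normexp 7183 and 4419. With no filter on dim probes 40824 features were tested, of which 10405 were higher and 3981 lower. Of 12748 genes well above background on all 8 arrays, 5347 were higher and 3543 lower. Spike-in scaling moved the median change of all genes from 0.11 to -0.34 (log2) in HCT116-/- and from 0.10 to -0.52 in MIAPaCa2. Directions are therefore relative to the 75th percentile of the array.

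Among the lists tested in HCT116-/-, genes of cholesterol synthesis were mostly higher, 21 of 25, with 2 lower and 2 not passing, and the counts were 21 and 2 adjusted over the list alone. MSMO1, a sterol oxidase, rose by 1.31 (SE 0.06) and STARD4, a sterol carrier, by 1.79 (SE 0.09), whereas TM7SF2, a sterol reductase, fell by 1.32 (SE 0.07). The adjusted p was 2.7e-04 by camera, and adjusted p = 0.23 with an estimated correlation. Of 33 mitosis genes 23 were higher and 5 lower (24 and 5 adjusted over the list alone). CCNA2, a cyclin, rose 2.83-fold and BIRC5, a survival and spindle protein, 2.93-fold, and CDC25B, a phosphatase of mitotic entry, fell by 1.90 (log2 SE 0.07, 0.06 and 0.07). By camera the adjusted p was 8.7e-04, and adjusted p = 0.23 with an estimated correlation. All 11 heat shock genes tested, of 12 listed, were higher (11 adjusted over the list alone). HSPA1A was well above background only on the HCT116-/- miR-766-5p arrays, so its rise there is set by the filter. The rises of DNAJB1 (0.26), HSPB1 (0.27) and BAG3 (0.42) are below the 0.45 by which spike-in scaling lowers every change in HCT116-/-, and the others are above it. DNAJA1, a co-chaperone, rose by 1.98 and HSPA8, a constitutive chaperone, by 1.07 (SE 0.07 each), and HSPA1A was at least 3.37-fold higher. For the list, camera gave adjusted p = 0.0010, and adjusted p = 0.23 with an estimated correlation.

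Of 16 NF-kB response genes 11 were higher and 2 lower in HCT116-/- (11 and 2 adjusted over the list alone), among them the chemokines CXCL1, which rose by 2.05 (SE 0.07), and CXCL3, by 2.30 (SE 0.09), and the mitochondrial superoxide dismutase SOD2, by 1.80 (SE 0.07). The camera test gave adjusted p = 0.031, adjusted p = 0.23 with an estimated correlation, and 0.070 after normexp. The unfolded protein and amino acid stress list was lower in 15 and higher in 7 of 31 genes (15 and 8 adjusted over the list alone). CHAC1, which degrades glutathione, fell by 2.85 (SE 0.09), DDIT4, an mTOR inhibitor, by 2.32 (SE 0.07) and DDIT3, a stress transcription factor, by 2.01 (SE 0.08). The adjusted p was 0.023 by camera, and adjusted p = 0.23 with an estimated correlation. Epithelial markers were lower in 10 and higher in 4 of 23 (10 and 4 adjusted over the list alone). ESRP2, a splicing factor, fell by 1.97 (SE 0.10) and KRT19, a keratin, by 1.16 (SE 0.09), and OCLN, a tight junction protein, rose by 1.01 (SE 0.08; 0.56 by the mean of its probes, limma adjusted p = 0.056). By camera the adjusted p was 0.0498, adjusted p = 0.29 with an estimated correlation, and 0.11 without HCT116-/- miR-NC replicate 1 or 0.13 without HCT116-/- miR-766-5p replicate 1. It was 0.070 after quantile normalization and 0.28 with spike-in scaling.

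In 3 further lists of HCT116-/- the median was below the 0.45 by which spike-in scaling lowers every change in that line, so it turned with that scaling, as that of any such list does. Of 34 ribosomal protein genes 23 were higher and 1 lower (23 and 1 adjusted over the list alone) with a median of 0.27, against 0 higher and 6 lower and a median of -0.18 with spike-in scaling. For the list, camera gave adjusted p = 0.0071, and adjusted p = 0.41 with an estimated correlation. RPL7 rose by 0.52 (SE 0.07) and RPL22 fell by 0.52 (SE 0.08). The other probes gave 0.30 and 0.32 for RPL7 (limma adjusted p = 0.083 each), and 0.0039 (not passing) and -1.55 for RPL22. RPL15 rose by 0.56 (SE 0.07) on its brighter probe and fell by 1.13 on the other. Of 13 housekeeping genes 10 were higher (10 adjusted over the list alone), TFRC, the transferrin receptor, by 1.07, SDHA by 0.57 and PPIA by 0.55 (SE 0.06, 0.07 and 0.07; 0.11 for PPIA by the mean of its probes, limma adjusted p = 0.22, since 1 of its 4 other probes fell by 1.29), with 1 higher and 4 lower after spike-in scaling. The camera test gave adjusted p = 0.023, and adjusted p = 0.28 with an estimated correlation. Of 31 genes of oxidative phosphorylation 19 were higher and 4 lower (19 and 4 adjusted over the list alone), against 8 and 9 with spike-in scaling. COX7B rose by 0.89, and ATP5F1C fell by 1.49 and NDUFB5 by 0.95 (SE 0.06 each). The adjusted p was 0.026 by camera, and adjusted p = 0.23 with an estimated correlation.

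Among genes with a symbol that were well above background on all 4 arrays of MIAPaCa2, CXCL8, a neutrophil chemokine, had the largest rise, 25.3-fold (log2 4.66, SE 0.19, n = 2 per group), and BIRC3, an inhibitor of apoptosis, rose 17.1-fold and IL20RB, a cytokine receptor subunit, 15.9-fold. S100A3 rose 19.9-fold, LINC01010 19.5-fold, SCARNA11, a small Cajal body RNA, 19.4-fold, CD82, a tetraspanin, 18.2-fold, EPB41L1 18.2-fold, CCDC126 14.6-fold and VAMP4 14.6-fold. POLR1G, a subunit of RNA polymerase I, fell by 5.03 (log2; SE 0.09), PLP2 by 4.72, ACTR3B by 4.65, TLCD1 by 4.37, HNRNPLL, a splicing regulator, by 4.15, TPGS2 by 4.02, GTPBP1 by 3.99, PRR13 by 3.98 and MYBPH by 3.94. The limma adjusted p of these genes lay between 1.1e-05 and 2.9e-04. Of genes measured in only 1 group, LINC00659 was at least 108-fold, ITPKB, an inositol kinase, at least 36.3-fold and LEMD1 at least 29.7-fold higher, while VPS9D1-AS1 was at least 32.6-fold, CEP41 at least 20.9-fold and PROSER1 at least 20.5-fold lower. The other probe of PROSER1 rose by 0.93 in MIAPaCa2 (limma adjusted p = 0.042). Other probes also gave smaller changes for ACTR3B (-1.50 and -1.63, the first as bright), HNRNPLL (-1.97), PRR13 (-1.58), VPS9D1-AS1 (-2.45) and VAMP4 (1.53). Of 3511 genes with several probes, 371 in HCT116-/- and 390 in MIAPaCa2 had probes passing in both directions. In MIAPaCa2 11206 of 18549 genes passed, 6122 higher and 5084 lower, of which 2689 and 2463 by at least 2-fold. With spike-in scaling 2542 were higher and 9328 lower, after quantile normalization 5261 and 5428, and after normexp 6808 and 4912. With no filter on dim probes, 10838 of 40824 features were higher and 4555 lower. Of 12748 genes well above background on all 8 arrays, 4973 were higher and 4248 lower.

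DNA replication genes fell together in MIAPaCa2, with 32 of 35 lower and 2 higher (32 and 2 adjusted over the list alone). PRIM1, the primase subunit, fell by 2.72 (SE 0.06), POLE2, a subunit of polymerase epsilon, by 2.69 (SE 0.09) and UHRF1, which couples replication to DNA methylation, by 2.08 (SE 0.07). By camera the adjusted p was 4.0e-10, and adjusted p = 0.037 with an estimated correlation. Of 56 MYC targets 46 were lower and 4 higher (47 and 4 adjusted over the list alone). The ribosome biogenesis genes RRP9, NOLC1 and TCOF1 fell by 2.61, 2.53 and 2.42 (SE 0.06, 0.07 and 0.06). For the list, camera gave adjusted p = 4.0e-10, and adjusted p = 0.049 with an estimated correlation. Histone genes and HEXIM1 were lower in 10 and higher in 2 of 12 (10 and 2 adjusted over the list alone), with H4C8 at -2.31, H2AC6 at -1.34 and H1-2 at -0.96. The camera test gave adjusted p = 0.0072, and adjusted p = 0.13 with an estimated correlation.

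All 16 NF-kB response genes tested, of 26 listed, rose in MIAPaCa2 (16 adjusted over the list alone). Among them were RELB, an NF-kB subunit, by 2.76 and NFKBIA, its inhibitor, by 2.69 (SE 0.07 each), besides BIRC3. TRAF1 was well above background only on the MIAPaCa2 miR-766-5p arrays, so its rise there is set by the filter. The adjusted p was 6.0e-08 by camera, and adjusted p = 0.047 with an estimated correlation. Of 29 genes of lysosome and autophagy 22 were higher and 2 lower (23 and 3 adjusted over the list alone), with MAP1LC3B, an autophagosome protein, at 2.07, WIPI1 at 2.05 and GABARAPL1 at 1.77. The list median was 0.72, against the 0.62 by which spike-in scaling lowers every change in MIAPaCa2. The counts therefore depend on the scaling. By camera the adjusted p was 9.1e-05, at most 6.6e-04 under the other scalings, and adjusted p = 0.063 with an estimated correlation. Of 19 genes of the BCL2 and IAP families 15 were higher and 3 lower (15 and 3 adjusted over the list alone). BMF is among the 15, though below background on all 4 arrays of that line. The pro-apoptotic BAK1 rose by 2.39 and the pro-apoptotic BCL2L11 fell by 2.99 (SE 0.06 each), and the anti-apoptotic BIRC3 rose. The 2 other probes of BCL2L11 fell by 0.70 and 0.33, so the size of its fall rests on the probe, and in HCT116-/- they rose by 1.14 and 0.55 while the printed probe fell by 0.30. For the list, camera gave adjusted p = 0.0055, and adjusted p = 0.12 with an estimated correlation.

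Interferon response genes were higher in 21 and lower in 5 of 32 in MIAPaCa2 (21 and 5 adjusted over the list alone). DDX60 is among the 21, though below background on all 4 arrays of that line. ISG20, an exonuclease, rose by 3.40 (SE 0.07), IFIH1, a sensor of double-stranded RNA, was at least 17.6-fold and RSAD2, an antiviral enzyme, at least 11.3-fold higher. The list median was 1.19, or 1.03 with the 5 genes measured in only 1 group set at their bound. The camera test gave adjusted p = 0.0087, and adjusted p = 0.14 with an estimated correlation. Of 24 immediate early and MAPK feedback genes 17 were higher and 4 lower (17 and 5 adjusted over the list alone). DUSP6, a phosphatase of ERK, rose by 3.23 and ETV5 by 1.95, and AREG, a growth factor, fell by 2.16 (SE 0.07, 0.06 and 0.06). The adjusted p was 0.022 by camera, adjusted p = 0.14 with an estimated correlation, and 0.056 after normexp.

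**Figure D2:**
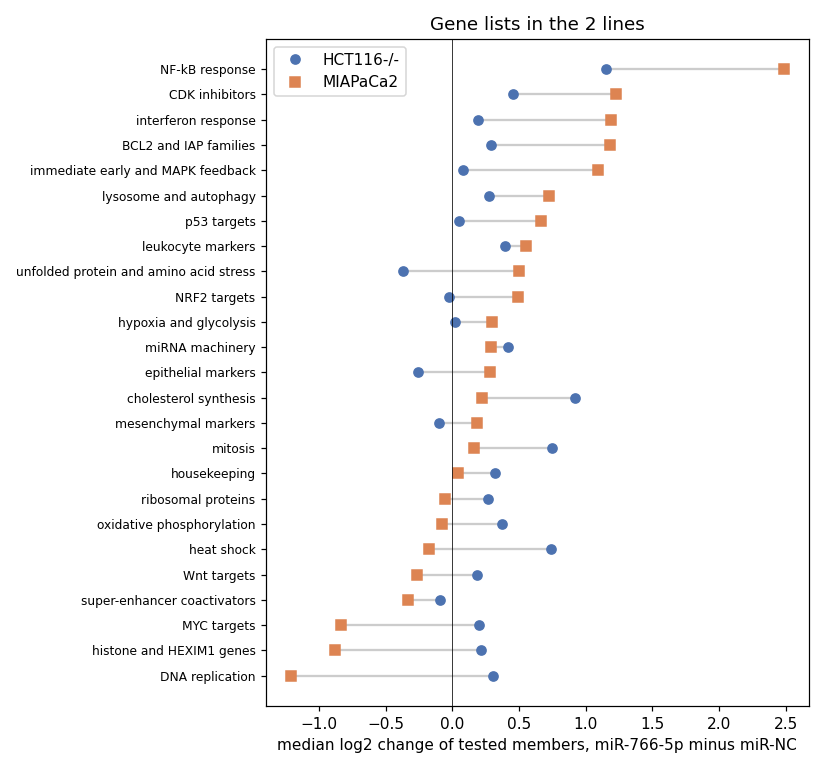
Median log2 change of the tested members (x axis) of each of 25 gene lists (y axis) with miR-766-5p against miR-NC, with circles for HCT116-/-, squares for MIAPaCa2 and a line joining them. The NF-kB response list had medians of 1.15 and 2.49, and the DNA replication list had a median of -1.21 in MIAPaCa2.

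The other lists tested did not pass in either line. Camera's adjusted p was 0.56 in HCT116-/- and 0.31 in MIAPaCa2 for super-enhancer coactivators, 0.67 and 0.31 for p53 targets, 0.30 and 0.061 for CDK inhibitors, 0.75 and 0.21 for hypoxia and glycolysis, 0.56 and 0.57 for NRF2 targets, 0.67 and 0.85 for miRNA machinery, 0.21 and 0.14 for leukocyte markers, 0.85 and 0.43 for mesenchymal markers, and 0.56 and 0.22 for Wnt targets. Median, mean and test differed in sign for Wnt targets in HCT116-/- (median 0.18, mean 0.30, test lower) and in MIAPaCa2 (median -0.27, mean 0.08, test lower), for mitosis in MIAPaCa2 (median 0.16, mean -0.18, test lower), for mesenchymal markers in HCT116-/- (median -0.10, mean 0.15, test higher), for heat shock in MIAPaCa2 (median -0.17, mean 0.01, test lower), for hypoxia and glycolysis in HCT116-/- (median 0.02, mean -0.01, test lower), for p53 targets in HCT116-/- (median 0.05, mean -0.01, test lower) and for immediate early genes in HCT116-/- (median 0.08, mean -0.05, test lower). Lists passing in 1 line had, in the other, adjusted p of 0.14 (DNA replication), 0.33 (MYC targets), 0.66 (histone genes and HEXIM1), 0.27 (lysosome and autophagy), 0.37 (BCL2 and IAP families), 0.94 (interferon response) and 0.67 (immediate early) in HCT116-/-, and 0.32 (cholesterol synthesis), 0.82 (mitosis), 0.50 (heat shock), 0.31 (ribosomal proteins), 0.62 (housekeeping), 0.21 (oxidative phosphorylation), 0.15 (unfolded protein and amino acid stress) and 0.76 (epithelial markers) in MIAPaCa2.

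Markers of the lines' tissues of origin (colon epithelium, pancreas and duct) and of other cell types were often below background. Of 13 colon epithelium markers 2 were tested, and CDX2, an intestinal transcription factor, fell by 0.40 in HCT116-/- and by 1.63 in MIAPaCa2 (SE 0.07). The other, CDX1, did not pass. Of 12 pancreas and duct markers 4 were tested. GATA6, a transcription factor, rose by 0.28 in HCT116-/- (limma adjusted p = 0.018) and was below background in MIAPaCa2, and KRT7 did not pass. SOX9, a duct transcription factor, fell by 1.03 and 0.52 (SE 0.08), and MUC1, a mucin, was at least 3.06-fold lower in MIAPaCa2. Of 10 fibroblast markers 3 were tested, with COL1A1 at least 4.205-fold lower in HCT116-/-, and COL1A2 rose by 0.36 in MIAPaCa2 (limma adjusted p = 0.0079), where COL3A1 was at least 1.325-fold lower. Of 8 endothelial markers 3 were tested, with ENG at least 6.75-fold lower in MIAPaCa2. VWF, a clotting factor carrier, rose by 1.18 in HCT116-/- (limma adjusted p = 0.0016) and was below background in MIAPaCa2, and ESAM did not pass. Of 12 leukocyte markers 6 were tested. CD14, a lipopolysaccharide receptor, rose by 2.83 in HCT116-/- and 1.04 in MIAPaCa2 (SE 0.07 each), and CD3D, a T cell receptor subunit, by 0.39 and 0.47 (SE 0.09 each). CD68, a lysosomal protein, rose by 1.28 in MIAPaCa2, and LCP1, an actin-bundling protein, by 1.12 in HCT116-/-, below background in MIAPaCa2. CD79A and PTPRC did not pass. The changes of GATA6, COL1A2 and CD3D are below the 0.45 (HCT116-/-) and 0.62 (MIAPaCa2) by which spike-in scaling lowers those of a line.

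The responses of the lines overlapped. Of 18549 genes, 3641 were higher in both lines, against 1941.7 for independent lists, and 2886 were lower in both, against 1253.4, which makes 6527 changed the same way. Another 1357 passed in opposite directions. The changes correlated across genes, which are not independent replicates, with Pearson r = 0.554 and Spearman rho = 0.520, and the lines share no control arrays. Both the counts and the correlation include genes below background on all 4 arrays of 1 line. COL1A2 passed so as higher in HCT116-/- (0.56), and COL1A1 as lower in MIAPaCa2 (-0.90). The overlap therefore does not rest on measured changes alone. ANKRD26P1, ACTA1, a skeletal muscle actin, NEURL3, TENT4B, a non-canonical poly(A) polymerase, and LINC01140 were below background on the miR-NC arrays of both lines and were at least 17.6-fold, 5.46-fold, 8.44-fold, 13.3-fold and 5.86-fold higher in MIAPaCa2. The same genes were at least 17.3-fold, 5.95-fold, 5.03-fold, 3.26-fold and 6.76-fold higher in HCT116-/-. MGAT4A, FRZB and KCNE5, a potassium channel subunit, rose in HCT116-/- and were at least 17.1-fold, 6.24-fold and 17.7-fold higher in MIAPaCa2.

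Among genes lower in both lines, XRN1, the cytoplasmic 5' to 3' exoribonuclease, fell by 3.96 (SE 0.73) in HCT116-/-, where 1 of 2 miR-766-5p arrays measured it, and was at least 6.88-fold lower in MIAPaCa2. MLLT6 fell by 2.10 and AGFG2 by 2.57 in HCT116-/- (the latter measured on 1 of 2 miR-766-5p arrays) and were at least 14.99-fold and 15.7-fold lower in MIAPaCa2. SLC25A10 and STRA6, a retinol transporter, were at least 14.3-fold and 20.0-fold lower in MIAPaCa2. In the additive fit over both lines (4 arrays against 4), 8853 genes passed in limma, 5026 higher and 3827 lower, or 1794 and 7834 with spike-in scaling.

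**Figure D3:**
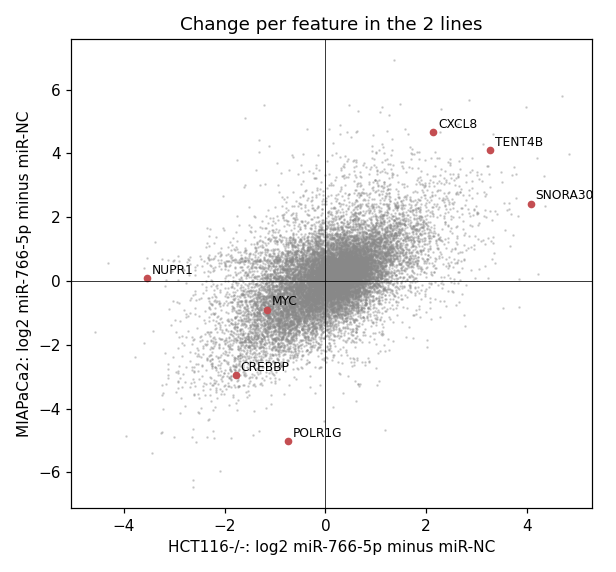
Log2 change with miR-766-5p in HCT116-/- (x axis) and MIAPaCa2 (y axis), with 1 grey point for each of 18549 genes and examples named in red. POLR1G lay at -0.74 and -5.03, and NUPR1 at -3.54 and 0.09.

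The size of the response differed between the lines for 7529 genes, 3482 with a higher and 4047 with a lower change in MIAPaCa2 (2658 and 5163 with spike-in scaling). CD70, a TNF family ligand, fell by 1.75 in HCT116-/- and rose by 3.78 in MIAPaCa2 (SE 0.19 each, n = 2 per group; limma adjusted p = 3.1e-04 for the difference). LEMD1 fell by 1.60 in HCT116-/- and was at least 29.7-fold higher in MIAPaCa2. LOC286297 was at least 11.6-fold and TM4SF19 at least 6.37-fold higher in MIAPaCa2, and LINC00659 had the bound given above. POLR1G fell by 0.74 in HCT116-/- against 5.03 in MIAPaCa2. NPTX1, a neuronal pentraxin, and NANOS1, an RNA-binding protein, were at least 7.94-fold and 4.22-fold lower in MIAPaCa2. HSPA2, a heat shock protein of the testis, rose by 2.78 in HCT116-/-, where 1 of 2 miR-NC arrays measured it, and was at least 2.29-fold lower in MIAPaCa2. RPRML fell by 2.07 in MIAPaCa2, and in HCT116-/- only 1 of 2 miR-766-5p arrays and no miR-NC array measured it.

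In lists, the difference between responses passed for 17 of 25. DNA replication was lower in MIAPaCa2 relative to HCT116-/- in 34 of 35 genes (35 adjusted over the list alone), MYC targets in 50 of 56 (51), mitosis in 27 of 33 (27), heat shock in 10 of 11 (11), oxidative phosphorylation in 16 of 31 (19) and histone genes and HEXIM1 in 10 of 12 (10). NF-kB response was higher in 13 of 16 (13), interferon response in 19 of 32 (20), unfolded protein and amino acid stress in 20 of 31 (20), immediate early genes in 16 of 24 (16) and lysosome and autophagy in 15 of 29 (15). These 11 held with an estimated correlation, at adjusted p between 0.016 and 0.037. The other 6 did not, with ribosomal proteins at adjusted p = 0.16, cholesterol synthesis at 0.16, BCL2 and IAP families at 0.085, p53 targets at 0.15, NRF2 targets at 0.20 and epithelial markers at 0.16 with an estimated correlation. Leaving out HCT116-/- miR-NC replicate 1 or HCT116-/- miR-766-5p replicate 1 ended the call of epithelial markers (0.056 and 0.061), and leaving out MIAPaCa2 miR-NC replicate 1 that of NRF2 targets (0.052). Ribosomal proteins had 0.14 after quantile normalization.

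The miR-NC arrays of the 2 lines differed at 12255 genes, 5031 higher in HCT116-/- and 7224 higher in MIAPaCa2. Each line lay in its own row of the slide, so line and row cannot be told apart in these counts. The split depends on the scaling, with 5907 and 5796 after spike-in scaling, 5981 and 5940 after quantile normalization and 4779 and 7896 after normexp. LDHB, a lactate dehydrogenase subunit, was at least 2246-fold and EPCAM, an epithelial adhesion molecule, at least 570-fold higher in HCT116-/-, with GTSF1 at least 506-fold, COL9A3 at least 318-fold and MAGEA2B at least 242-fold. CBS, a cystathionine synthase, was at least 2235-fold, ALDH1A1, a retinal dehydrogenase, at least 730-fold, SRGN at least 707-fold, CLDN11 at least 685-fold and GSTM3 at least 519-fold higher in MIAPaCa2 (limma, n = 2 per group; adjusted p between 5.17e-07 and 1.75e-05).

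**Figure D4:**
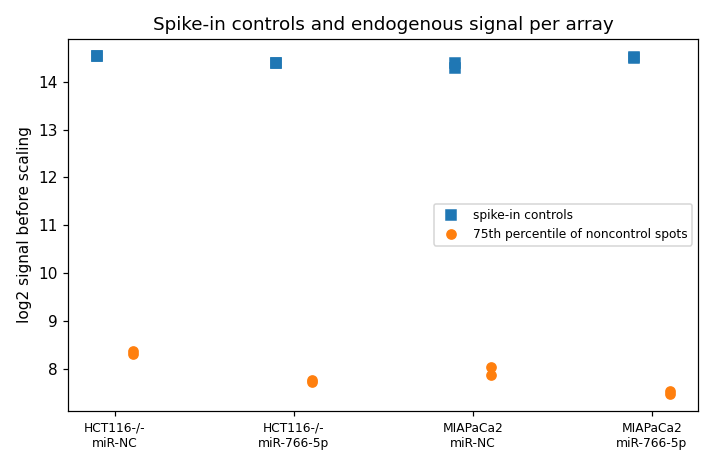
Log2 signal before scaling (y axis) of the 5 brighter spike-in controls (squares) and of the 75th percentile of noncontrol spots (circles) on each of the 8 arrays, by group (x axis). The 75th percentile was lower on the miR-766-5p arrays of both lines, by -0.60 and -0.45, while the spike-in signal changed by -0.16 and 0.17.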

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

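The tests of array-wide brightness, of less endogenous RNA and of slide position were chosen after the result was seen.

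Of 114 named genes, 98 differed between MIAPaCa2 and HCT116-/- in their change with miR-766-5p by the interaction of the 4-group limma fit (n = 2 per group). Most were named for large changes, so this share is set by that choice, and over all genes 7529 of 18549 differed. Values in brackets are the MIAPaCa2 change minus the HCT116-/- change (log2). Among genes well above background on all 8 arrays, the change was higher in MIAPaCa2 for NUPR1 (3.63), R3HDM2 (2.23), IDNK (1.14), CXCL8 (2.52), S100A3 (4.17), SCARNA11 (1.15), CD82 (3.04), EPB41L1 (2.51), BIRC3 (2.78), IL20RB (4.44), CCDC126 (1.60) and VAMP4 (2.94). So it was for CD70 (5.53), CXCL3 (0.77), OCLN (1.01), KRT19 (0.90), DDIT4 (1.06), CHAC1 (0.50), DDIT3 (3.61), BAK1 (1.74), RELB (1.4997), NFKBIA (2.004), DUSP6 (3.44) and ETV5 (1.47). This also held for ISG20 (3.64), GABARAPL1 (1.09), MAP1LC3B (0.85) and WIPI1 (3.01). It was lower in MIAPaCa2 for SNORA30 (-1.66), SNORA2B (-1.61), SNORA48 (-1.37), SNORA67 (-1.98), SNORA6 (-1.30), SNORA13 (-1.18), SNORA51 (-1.39), PLP2 (-1.48), TPGS2 (-0.80), POLR1G (-4.29) and ACTR3B (-2.02). So it was for TLCD1 (-2.03), HNRNPLL (-1.63), GTPBP1 (-2.81), PRR13 (-1.52), MYBPH (-4.09), CXCL1 (-0.42), DNAJA1 (-0.63), HSPA8 (-1.65), TFRC (-0.55), PPIA (-0.71), SDHA (-0.58) and CDC25B (-0.86). This also held for BIRC5 (-0.36), CCNA2 (-1.14), ATP5F1C (-0.35), NDUFB5 (-0.30), COX7B (-0.96), RPL15 (-0.45), RPL7 (-0.62), RPL22 (-0.75), BCL2L11 (-2.69), PRIM1 (-1.18), POLE2 (-1.67) and UHRF1 (-1.96). So it was for RRP9 (-1.75), NOLC1 (-2.20), TCOF1 (-1.78), H4C8 (-1.64), H2AC6 (-1.28), H1-2 (-1.91) and AREG (-1.17). These values are of 1 probe per gene. The other probe of CXCL1 had the opposite order, with a rise of 1.08 in HCT116-/- and 2.44 in MIAPaCa2, and so had 1 of 2 other probes of RPL22 (0.31 in MIAPaCa2, not passing).

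Other named genes were below background on at least 1 array, so their fitted difference is no bound. It was higher in MIAPaCa2 for ABCC3 (2.22), KRCC1 (2.97), LINC01010 (3.17), LINC00659 (5.55), ITPKB (4.06), LEMD1 (6.70), KCNE5 (2.81), NEURL3 (2.26), LOC286297 (6.72), TM4SF19 (5.75), ESRP2 (1.55), IFIH1 (4.24) and RSAD2 (4.70). It was lower there for CA8 (-2.63), SLC25A10 (-1.95), STRA6 (-1.88), VPS9D1-AS1 (-3.82), CEP41 (-2.70), PROSER1 (-3.60), MLLT6 (-3.84), AGFG2 (-2.49), NPTX1 (-5.85), NANOS1 (-4.36), HSPA2 (-4.20) and RPRML (-4.09). So it was for CREBBP (-1.18), STARD4 (-1.15) and HSPA1A (-2.70). The other probe of PROSER1 rose by 0.93 in MIAPaCa2 and changed by -0.21 in HCT116-/- (not passing), so its direction rests on the probe.

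Of 25 lists, 17 differed between the lines by camera with the preset correlation. With an estimated correlation 11 of the 17 held, and the adjusted p of the other 6 was 0.085 (BCL2 and IAP families), 0.15 (p53 targets), 0.16 (cholesterol synthesis, epithelial markers and ribosomal proteins) and 0.20 (NRF2 targets). Values in the following brackets are the median difference of their members. They were higher in MIAPaCa2 for BCL2 and IAP families (0.95), NF-kB response (1.64), NRF2 targets (0.44), epithelial markers (0.34), immediate early and MAPK feedback (0.79), interferon response (1.19), lysosome and autophagy (0.48), p53 targets (0.45) and unfolded protein and amino acid stress (0.70). They were lower for DNA replication (-1.40), MYC targets (-1.01), cholesterol synthesis (-0.34), heat shock (-0.79), histone and HEXIM1 genes (-1.22), mitosis (-0.84), oxidative phosphorylation (-0.39) and ribosomal proteins (-0.37).

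The spike-in controls, used only where spike-in scaling is named, rose against the 75th percentile of the array with miR-766-5p by 0.45 (log2, SE 0.036) in HCT116-/- and by 0.62 (SE 0.044) in MIAPaCa2. A brighter or dimmer array would move both alike, so the smaller difference of 0.45 argues against brightness alone. The share of spots well above background changed by -3.77 percentage points in HCT116-/- and by -4.00 in MIAPaCa2, which less endogenous RNA per labelled RNA would give. In HCT116-/- the share was 46.8% and 49.0% with miR-NC and 45.8% and 42.5% with miR-766-5p. In MIAPaCa2 it was 45.8% and 44.0%, and 41.9% and 39.9%. The 2 arrays of a group thus differed as well, and the change in this share was not tested. The labels give the RNA input but not the amount of spike-in, so a difference in added spike-in and a change of cellular RNA cannot be told apart here.

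The shared response of both lines was set against the place of the arrays on the slide. A gradient over array columns, estimated within groups, gave 1.59% of the shared change in MIAPaCa2 and 0.694% in HCT116-/-, which argues against a gradient. A step between columns 2 and 3 stays open, because it divides the arrays as the transfection does. Of 34 splits of the 8 arrays into 4 and 4 that could be fitted, 1, the real one, gave as many genes in the additive fit (8853, against 38 in the highest other). The split with 38 genes was the only other one that kept the 2 arrays of each group together. All further fitted splits parted these arrays and left differences between groups in the residual. They would call few genes whatever made the groups differ, so this test cannot decide on chance. It also says nothing of chance differences between single cultures or transfections. The 1 split that could not be fitted follows the cell line, and the transfected miR-766-5p stays among the open explanations.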

How the results depend on the processing

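Scaling to the spike-in controls was chosen after seeing the data, as was the signal column for normexp, and the other alternatives were planned. Of the results for named genes over all alternatives, 3406 kept their direction and their side of the threshold, 31 no longer passed and 2 turned. For lists, by the direction of the list test, these were 1029, 37 and 14, and 45 newly passed. Most named genes were chosen for large changes, so their stability is set by that choice. Over all genes, spike-in scaling kept 7128 of 10456 calls the same way in HCT116-/- and 7625 of 11206 in MIAPaCa2. Except where stated, the cause was not tested.

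Requiring a change of at least 2-fold left 3945 genes in HCT116-/-, 5152 in MIAPaCa2, 3462 for the difference between responses, 3834 over both lines, 6538 between the miR-NC arrays of the lines and 2104 changed the same way. The test against a 1.5-fold change left 3751, 5135, 2417, 2819, 6784 and 2113 in that order. Both are stricter by construction. With no filter on dim probes, 4457 of 40824 features passed for the difference between responses and 15449 over both lines.

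Leaving out each array in turn gave 8405 to 10496 genes in HCT116-/-, 9882 to 11191 in MIAPaCa2, 5928 to 6764 for the difference between responses, 7679 to 8104 over both lines, 10704 to 12275 between the miR-NC arrays of the lines and 5507 to 6062 changed the same way. The lone array left in a group is assumed to vary like the other groups. Lists passing ranged from 8 to 9, from 8 to 9 and from 16 to 17. The median of the interferon list in HCT116-/- ranged from 0.085 to 0.28, and that of the leukocyte list for the difference between responses from -0.43 to 0.15, neither passing.

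Of 9 lists passing in HCT116-/-, 5 passed after quantile normalization, 5 after normexp, 5 with spike-in scaling, 0 with an estimated correlation (24 by fry). In MIAPaCa2, 3 of 8 passed with an estimated correlation (24 by fry), and 11 of 17 for the difference between responses. Fry compares no list with other genes. In HCT116-/- adjusted p rose to 0.59 after quantile normalization, 0.23 after normexp and 0.87 with spike-in scaling for housekeeping, to 0.59, 0.28 and 0.45 for oxidative phosphorylation, and to 0.93, 0.17 and 0.88 for ribosomal proteins.

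RPL15 turned to -0.28 in HCT116-/- with the mean of a gene's probes, because its other probe fell. With spike-in scaling RPL30 turned to -0.023, the ribosomal list to -0.18 and the MYC list to -0.24 in HCT116-/-, and the housekeeping list to -0.58 in MIAPaCa2. The lists named here turned in their test, and the values given are medians. That scaling lowers all changes of a line by 1 constant. Medians of other lists turned with it as well, among them those of housekeeping and oxidative phosphorylation genes in HCT116-/-. After quantile normalization the ribosomal list in HCT116-/- turned to -0.011, and the interferon list's test turned at a median of 0.027. After normexp the test of miRNA machinery turned (median 0.18 in HCT116-/-, 0.20 in MIAPaCa2) and the housekeeping list went to -0.062 in MIAPaCa2.

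The same-numbered arrays of a line showed no pairing (correlation of deviations 0.012 in HCT116-/- and -0.0063 in MIAPaCa2). With the replicate number as a block, 9567, 10431, 5908, 6526 and 10337 genes passed in the comparisons in the order above, 5852 changed the same way, and the test of mesenchymal markers in HCT116-/- turned at a median of -0.10. The tests of seed sites were not run. Signal over background limits the folds of genes measured in only 1 group to bounds.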

Other observations

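The tests of snoRNA scaling were chosen after the result was seen, and so was this class of genes.

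Changes of small nucleolar and Cajal body RNAs are relative to the 75th percentile of the array, and no test set them against other genes. Of 97 H/ACA RNAs tested, 85 were higher and 5 lower in HCT116-/- (median 1.13) and 77 were higher and 7 lower in MIAPaCa2 (median 0.83; 47 and 20 with spike-in scaling). All 22 Cajal body RNAs were higher in HCT116-/- (median 1.55) and 20 in MIAPaCa2 (1.56). Of 112 C/D RNAs 85 were higher, 1 lower and 26 not passing in HCT116-/- (0.86), and 47, 6 and 59 in MIAPaCa2. There the median of 0.27 turned to -0.35 with spike-in scaling, a step that took all genes from 0.10 to -0.52. XRN1 and TOE1, both nucleases, were lower in the additive fit over both lines (-1.09 for TOE1, SE 0.18; XRN1 has only the values given in the report), and TENT4B, which adds oligo(A) tails to nuclear RNAs, was higher by the bounds given in the report. Genes of H/ACA proteins did not agree. NOP10 rose in both lines (0.56 and 0.63), NHP2, DKC1 and GAR1 rose in HCT116-/- (0.78, 0.36 and 0.23) and fell by 0.55, 0.48 and 0.29 in MIAPaCa2, and NAF1 and SHQ1 did not pass in either line, though SHQ1 rose in the additive fit (0.57, limma adjusted p = 0.021). PARN, a deadenylase, rose by 0.26 in HCT116-/- and fell by 0.83 in MIAPaCa2. The rises of DKC1, GAR1 and PARN are below the 0.45 by which spike-in scaling lowers all changes in HCT116-/-.

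These RNAs were compared with the RNA level of the genes that hold them in their introns. This covered 207 RNAs in 127 host genes, by spans in the GRCh38.p14 table without strand. The median RNA minus host change was 0.90 (SE 0.14) in HCT116-/- and 0.86 (SE 0.18) in MIAPaCa2, so in the median they rose more than the RNA of their hosts. Each SE in this paragraph is that of a median across host genes or RNAs, which are not independent replicates. It is not that of the fit and does not measure the spread between arrays. The arrays measure RNA level and not transcription, so host transcription as a cause stays open. With spike-in scaling the median of all 231 was 0.55 (SE 0.080) in HCT116-/- and -0.087 (SE 0.082) in MIAPaCa2, so scaling stays open for the direction in MIAPaCa2, though not for the lead over all genes (medians -0.34 and -0.52), which 1 constant per line leaves as it is. More non-polyadenylated RNA in the labelled pool also stays open. The 14 other small RNAs had medians of 0.56 (SE 0.23) in HCT116-/- and 0.35 (SE 0.36) in MIAPaCa2. In MIAPaCa2 6 of them were higher, 1 was lower and 7 did not pass, so they cannot decide there.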
